A study of Mus musculus with 6 samples.

How the data were processed

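Gene expression was measured by RNA-seq of polyadenylated RNA in granulocyte-monocyte progenitors, bone marrow cells that give rise to neutrophils and monocytes. The cells were sorted from wild-type mice on day 3 after myocardial infarction, the death of heart muscle after its blood supply is blocked. Of the 6 libraries, 3 came from control mice with infarction and 3 from mice that had also undergone sleep fragmentation, and groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with a column kit for small inputs and libraries were made with the VAHTS Universal V6 kit. The labels do not say whether a library held cells of 1 mouse or of several, so p-values measure only the spread between these libraries, part of which may be technical.

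The deposited table holds raw read counts per gene, with gene symbols and Entrez Gene numbers. Per the submitters' processing notes, fastp, HISAT2 and HTSeq were used with the mouse build GRCm39. Their versions, the strand setting and the annotation release were not given in the sources used here. The values of each column were whole numbers, and the columns summed to different totals, between 28971253 and 31665923. Without a stated strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart. Reads that match several near-identical genes can be dropped or assigned to the wrong copy at counting, which bears on the Ifit, Ifi200, Oas, Slfn, Gbp, stefin A, ribosomal protein and H2 families. Values of their single members are therefore uncertain. No coordinates are given, because the reference genome at hand was of another build.

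The table listed 16539 genes, of which 653 had no read in any library. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default minimum count of 10 and minimum total of 15, which left 12097 genes. Library sizes were scaled by TMM factors, which lay between 0.910 and 1.086. Dispersions were estimated with estimateDisp, and the groups were compared with the robust quasi-likelihood F-test, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The fit had 4 residual degrees of freedom and a common biological coefficient of variation of 0.206. Expression is given as CPM, the count scaled to 1e+06 counts of the TMM-scaled library. Log2 fold changes are for sleep fragmentation against control and are given with their standard error (SE), and means are given with the standard deviation (SD, n = 3 per group).

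Before the data were examined, 34 gene lists were fixed from general knowledge: interferon responses, granule and neutrophil genes, lineage markers, cell cycle, metabolism, stress, clock and glucocorticoid genes, markers of other marrow cells and signs of RNA quality. Late granule genes stand here for a list of genes of secondary and tertiary granules and other genes of maturing neutrophils, among them receptors, cytokines and a transcription factor. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and adjustment over the 32 lists tested. The list of mitochondrially encoded genes and that of sex-linked genes had too few tested members and were not analysed here. Camera with an estimated correlation and the fry rotation test were run beside it. Members of each list were also adjusted over the list alone. A list score is the mean log2 CPM of the members (prior count 2) minus its mean over the 6 libraries. Scores were compared by a 2-sided exact permutation test, whose smallest possible p with 3 against 3 libraries is 0.1. Terms of the Gene Ontology (GO), as the deposited table assigns them, were tested by camera where they held 10 to 300 tested genes.

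The genes named were chosen by a rule fixed at the same time. It took up to 10 genes per direction with the largest change among those past the threshold, with a mean CPM of at least 5 and no overlap between the groups. Where fewer than 5 passed, it added those with the smallest p up to 5, named as not passing, under the same limits on level and overlap. It also took 15 genes in any case and up to 4 members with the smallest p of each list reported. Some genes the rule takes are not reported here. Other genes are named only to complete a count or to say what a list holds, and were chosen after their values were seen.

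The test was checked on counts simulated from the means, dispersions and library sizes of these 6 libraries, in 5 runs with 200 of 12097 genes changed. The changed genes were drawn only from those with an average CPM of at least 5. Of these, the test recovered 17.3% of genes changed 1.5-fold, 81.5% of those changed 2-fold and 100.0% of those changed 4-fold. Of its calls 8.95% were false. Recovery of genes at lower levels was not checked. Depth was alike in all libraries, and counting error was small beside the spread between replicates for all but the lowest genes. Replicates of a group differed by far more than sampling noise, with a chi-square per degree of freedom between 28.0 and 203.3, so none was treated as a repeat deposit of another library. This does not show that they came from separate animals.

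Alternatives were other scaling factors (relative log expression, upper quartile, library size only), DESeq2 1.42.0, limma-voom, no filter or a stricter filter on low counts, no robust estimation, the replicate number as a block, each library left out in turn, other thresholds, and other gene set tests. A pair of alternatives was added after the data had been seen: leaving out replicate 1 of both groups, and a score of late granule genes as a covariate.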

Results

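The data were RNA-seq read counts of granulocyte-monocyte progenitors sorted from mouse bone marrow on day 3 after myocardial infarction. Libraries came from 3 control samples and from 3 samples of mice with sleep fragmentation, in which sleep is interrupted again and again. The design text names proliferation of these progenitors and their differentiation into neutrophils, which read counts do not measure directly. The study's title names type I interferon and neutrophils with high SiglecF. Total counts were 30612583, 31665923 and 30297437 in control replicates 1 to 3, and 29398665, 30702452 and 28971253 in sleep fragmentation replicates 1 to 3. Between 14047 and 14265 genes had a count in each library. The 10 most abundant genes took between 7.62% and 13.1% of the counts.

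Sleep fragmentation was compared with control over 12097 genes. The genes with the smallest p among those higher after sleep fragmentation included 3 interferon-stimulated genes. Ifit1, an antiviral protein that binds foreign RNA, had 1.43 ± 0.84 CPM (SD, n = 3) in control and 9.38 ± 4.52 CPM (SD, n = 3) after sleep fragmentation, a log2 fold change of 2.71 (SE 0.53). Xaf1, an interferon-inducible regulator of apoptosis, had 4.66 ± 1.42 against 12.3 ± 1.87 CPM (log2 fold change 1.40, SE 0.26). Ifi204, of the family of DNA-sensing interferon-inducible proteins, had 11.5 ± 3.41 against 30.5 ± 7.62 CPM (log2 fold change 1.41, SE 0.26). The other genes taken by the rule on this side were Gpr27, an orphan receptor, with 8.71 ± 0.38 against 22.4 ± 7.33 CPM, and Stfa2l1, of the stefin A family of protease inhibitors, with 11.8 ± 5.02 against 32.8 ± 8.42 CPM. On the lower side, differences were smaller. Zkscan1, a zinc finger gene, had 30.8 ± 2.62 CPM in control and 22.2 ± 2.30 CPM after sleep fragmentation (log2 fold change -0.47, SE 0.14). Gmppa, Ptar1, Tmem250-ps and Yif1b had log2 fold changes of -0.41, -0.35, -0.40 and -0.40, each with non-overlapping groups.

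None of these differences passed edgeR's quasi-likelihood test over all genes (adjusted p = 0.99988 for each). That test called 0 genes at an adjusted p under 0.05, with 341 genes at an unadjusted p under 0.05 (2.82%, where chance gives 5%), 261 of them higher and 80 lower after sleep fragmentation. Single libraries moved the count at an unadjusted p under 0.05: it was 155 of 12300 tested genes without control replicate 1, 761 of 12323 without control replicate 2, 204 of 12295 without control replicate 3, 1330 of 12284 without sleep fragmentation replicate 2 and 197 of 12307 without sleep fragmentation replicate 3, so that it lay above the share chance gives without replicate 2 of either group, with 0 genes called in each case. It was 796 of 12097 with the score of late granule genes as a covariate, an alternative chosen after the data were seen. limma-voom also called 0 genes, with 338 at an unadjusted p under 0.05. DESeq2 called 13 genes, 12 higher and 1 lower, from 443 at an unadjusted p under 0.05. Of the 13, 8 were on the interferon-stimulated list: Ifit1, Ifit3b, Xaf1, Ifi204, Rsad2, Rtp4, Oasl2 and Zbp1. The others, which the rule did not all take, were Gpr27, Stfa2l1, Klra2 and Vnn3, which were higher, and Capn11, which was lower. The groups did not overlap in 817 genes (6.75%, where chance gives 10%), 353 of them higher and 464 lower.

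Interferon-stimulated genes had the smallest camera p of the 32 lists tested. Of 72 tested members of the list, 69 had higher fitted levels after sleep fragmentation, and the median log2 fold change was 0.56, a 1.47-fold difference. Adjusted over the list alone, 22 members rose and 0 fell, whereas 0 passed edgeR's test adjusted over all genes tested, and 37 higher and 0 lower members had an unadjusted p under 0.05. The 22 included Ifit1, Xaf1 and Ifi204 (edgeR p adjusted over the list alone 0.016 for each) and Ifit3b, which had 0.44 ± 0.22 CPM in control and 4.99 ± 4.59 CPM after sleep fragmentation. They also held Irf7, the transcription factor that amplifies type I interferon production, at 11.5 ± 3.48 against 27.9 ± 17.8 CPM, and Isg15, a ubiquitin-like modifier, at 2.57 ± 0.82 against 5.96 ± 2.94 CPM (edgeR p adjusted over the list alone 0.049 for both). Camera with its preset correlation called the list (adjusted p = 1.4e-34), which was lost at adjusted p = 0.53 with an estimated correlation and at adjusted p = 0.70 with fry. List scores of the 3 control libraries lay between -0.66 and -0.14 and those of the 3 sleep fragmentation libraries between 0.16 and 0.78. This is the smallest p an exact permutation test allows here (p = 0.1, 2-sided). Of the 32 lists, camera with its preset correlation called 13 with the labels as given. It called between 10 and 23 in the other splits of the 6 libraries into 3 and 3. Such a call therefore does not by itself set the labelled groups apart from other groupings.

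Single libraries weighed on the interferon-stimulated genes. Without sleep fragmentation replicate 1 the median was 0.33, and the number of members that passed, adjusted over the list alone, was 8. It was 2 without control replicate 1, 10 without sleep fragmentation replicate 3 and 34 without sleep fragmentation replicate 2, and 13 with no filter on low counts. With alternatives chosen after the data were seen, it was 4 without replicate 1 of both groups (median 0.28) and 5 with the score of late granule genes as a covariate (median 0.44).

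**Figure D1:**
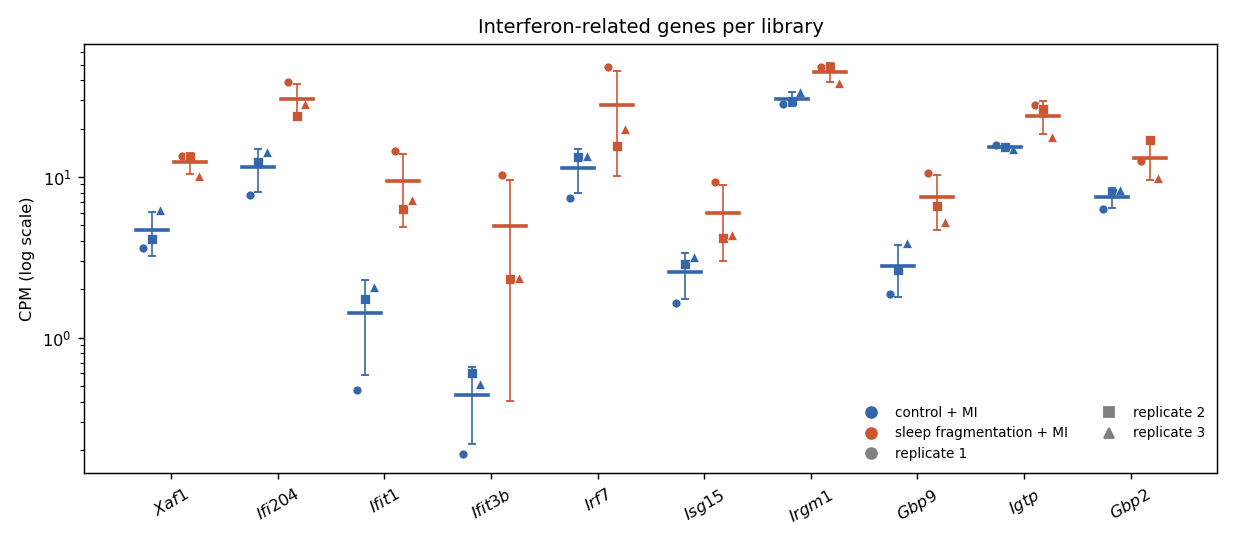
CPM of 10 interferon-related genes in each library, on a log axis. Symbols are replicates, horizontal lines are group means and error bars are SD (n = 3 per group). Irf7 lay between 7.45 and 13.6 CPM in the control libraries and between 15.5 and 48.3 CPM after sleep fragmentation.

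The list of interferon-gamma-inducible genes held mostly GTPases that act against pathogens inside cells, but also Socs1, an inhibitor of cytokine signalling, the transcription factor Irf1, the chemokine Cxcl9, Ciita, the transactivator of MHC class II, and Cd274, which encodes PD-L1. Of 19 tested members 18 had higher fitted levels, with a median log2 fold change of 0.81. Adjusted over the list alone, 4 rose, namely the GTPases Irgm1 (30.7 ± 2.94 against 45.1 ± 5.80 CPM), Gbp9 (2.79 ± 1.01 against 7.47 ± 2.77 CPM), Igtp (15.4 ± 0.38 against 24.1 ± 5.58 CPM) and Gbp2 (7.51 ± 1.05 against 13.1 ± 3.60 CPM), and 0 passed over all genes tested by edgeR, with 9 higher at an unadjusted p under 0.05. Camera gave an adjusted p of 2.5e-10, lost at adjusted p = 0.52 with an estimated correlation. Without sleep fragmentation replicate 2 the median was 0.50. It was 0.56 with a stricter filter on low counts and 1.03 with no filter, so it depended on members with few reads. All 20 tested genes of antigen presentation by MHC class I had higher fitted levels, with a median log2 fold change of 0.21. Of these 0 passed edgeR's test, adjusted over the list alone or over all genes, with 2 at an unadjusted p under 0.05, H2-T24 (24.5 ± 6.98 against 55.6 ± 23.3 CPM) and H2-T23 (78.3 ± 9.20 against 102.4 ± 21.6 CPM). Psmb9, a subunit of the immunoproteasome, had 51.2 ± 2.61 against 59.4 ± 5.05 CPM, and H2-Q7 had 1.60 ± 0.68 against 3.16 ± 1.77 CPM. Camera called this list (adjusted p = 2.7e-06), lost at adjusted p = 0.53 with an estimated correlation, and the call also ended without sleep fragmentation replicate 2 (median 0.12). Its median was 0.11 when scaled by library size only. Ifnar1, a subunit of the type I interferon receptor, had 67.9 ± 6.14 CPM in control and 68.5 ± 5.55 CPM after sleep fragmentation.

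Neutrophil differentiation was followed through genes of granules, which are made in a fixed order as the cells mature, and of maturing neutrophils. The list of late granule genes held genes of secondary and tertiary granules and other genes of maturing neutrophils, among them Cebpe, the receptors Csf3r and Cxcr2 and the cytokine Il1b. These mostly had higher fitted levels after sleep fragmentation, with 46 of 47 fitted levels higher and a median log2 fold change of 0.62. Adjusted over the list alone, 1 rose (Stfa2l1), and 0 passed over all genes tested by edgeR, with 12 higher and 0 lower at an unadjusted p under 0.05. Ccl6, a chemokine, had 66.4 ± 15.2 against 103.0 ± 19.8 CPM, Fpr2, a receptor for bacterial peptides, 113.0 ± 34.5 against 243.9 ± 117.7 CPM, and Retnlg, a secreted protein of maturing neutrophils, 661.5 ± 336.5 against 1415 ± 433.6 CPM. Camera called the list (adjusted p = 2.1e-20), lost at adjusted p = 0.58 with an estimated correlation. The libraries of a group differed widely: control replicate 2 had a list score of 0.20 beside -0.53 and -0.62 in its group, and sleep fragmentation replicate 2 had -0.28 beside 0.78 and 0.44. The groups overlapped (exact permutation p = 0.2, 2-sided), and without sleep fragmentation replicate 1 the median was 0.33, or 0.20 without replicate 1 of both groups.

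Genes of primary granules, which are made by the progenitors themselves, had a median log2 fold change of -0.15, with 8 of 27 fitted levels higher. Mpo, myeloperoxidase, had 10849 ± 839.6 CPM in control and 9219 ± 2123 CPM after sleep fragmentation, and Elane, neutrophil elastase, 2888 ± 36.4 against 2489 ± 388.4 CPM. Prtn3, proteinase 3, had 2008 ± 94.1 against 1574 ± 167.6 CPM, Dmkn 37.1 ± 7.22 against 26.1 ± 2.75 CPM, and Mgst1 161.9 ± 40.3 against 236.2 ± 68.7 CPM. By edgeR 0 members passed, adjusted over the list alone or over all genes, with 1 lower (Dmkn) at an unadjusted p under 0.05. Camera called the list lower (adjusted p = 0.030), lost at adjusted p = 0.71 with an estimated correlation. The call also ended without control replicate 1 (median -0.08), control replicate 2 (-0.12) or sleep fragmentation replicate 1 (-0.04), and the median was -0.25 when scaled by library size only. It ended, with a positive median, without replicate 1 of both groups (0.028) and with the late granule covariate (0.016).

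Regulators of the choice between neutrophil and monocyte did not differ by more than the spread between replicates. Csf3r, the receptor of granulocyte colony-stimulating factor, had 426.2 ± 107.9 against 499.9 ± 131.2 CPM, and Cebpe, a transcription factor of granule genes, 217.4 ± 72.4 against 250.9 ± 67.1 CPM, both also on the list of late granule genes. Gfi1, which favours the neutrophil fate, had 164.0 ± 20.6 against 160.5 ± 21.97 CPM, and Irf8, which favours the monocyte fate, 176.9 ± 44.7 against 153.9 ± 41.3 CPM. Over 34 monocyte lineage genes the median log2 fold change was -0.01, and camera did not call them (adjusted p = 0.69). Camera called them higher without control replicate 3 (median 0.06, adjusted p = 0.020) and with the late granule covariate (0.16, adjusted p = 0.0077). Of these 0 passed edgeR's test, adjusted over the list alone or over all genes, with 1 higher at an unadjusted p under 0.05, Pira2, a receptor of myeloid cells (5.43 ± 2.17 against 9.60 ± 2.61 CPM). Rassf4, Clec4a1 and Ctss had log2 fold changes of -0.29, 0.43 and 0.24.

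**Figure D2:**
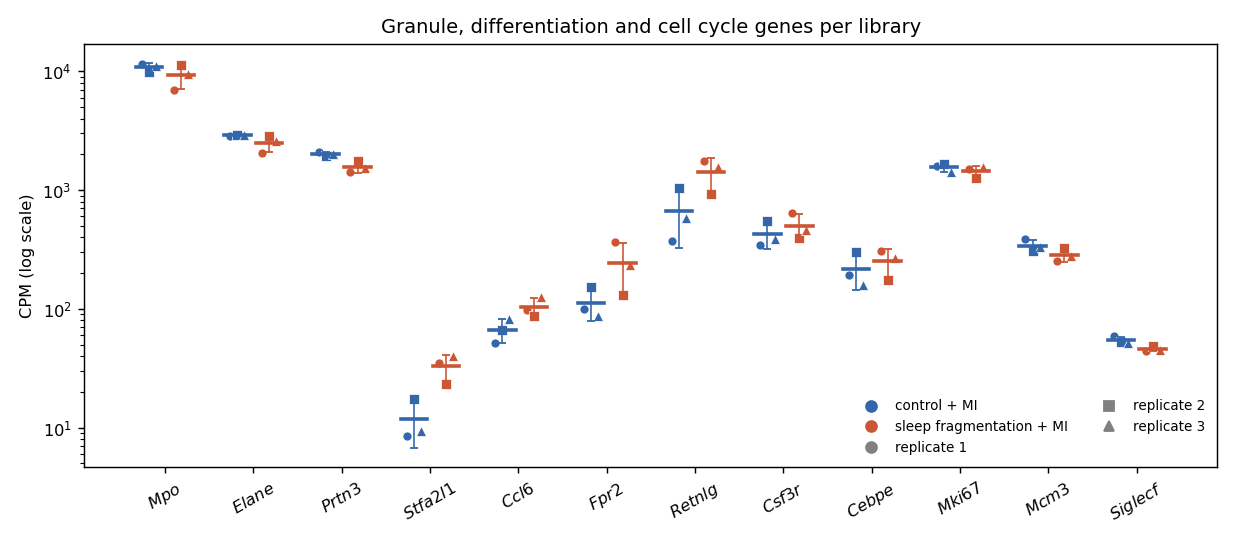
CPM of 12 genes of granules, differentiation and the cell cycle, Siglecf included, in each library, on a log axis. Symbols are replicates, horizontal lines are group means and error bars are SD (n = 3 per group). Retnlg was at 1032 CPM in control replicate 2 and at 928.5 CPM in sleep fragmentation replicate 2, so that its groups overlapped.

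Most genes of the cell cycle had slightly lower fitted levels after sleep fragmentation. Mki67, a marker of cycling cells, had 1551 ± 123.1 CPM in control and 1448 ± 154.1 CPM after sleep fragmentation. Of 52 S phase genes 3 had higher fitted levels, and their median log2 fold change was -0.11. Examples were Mcm5 (350.0 ± 14.8 against 303.7 ± 5.79 CPM) and Mcm3 (341.6 ± 39.9 against 284.9 ± 36.1 CPM), subunits of the replicative helicase, and Brip1 and Dscc1 (log2 fold changes -0.25 and -0.33). Of 58 genes of G2 and M phase 17 had higher fitted levels, with a median of -0.05. Among them Nek2, a kinase of centrosome separation, had 43.5 ± 2.23 against 36.2 ± 0.91 CPM, and Plk1, Kif2c and Gas2l3 had log2 fold changes of -0.20, -0.14 and -0.13. In both lists 0 members passed edgeR's test, adjusted over the list alone or over all genes, with 0 S phase genes and 1 G2 and M phase gene (Nek2) at an unadjusted p under 0.05. Camera called both lower, at adjusted p = 5.6e-07 for S phase and 0.019 for G2 and M phase, and both were lost with an estimated correlation (adjusted p = 0.58 and 0.73 with an estimated correlation). Without control replicate 1 or without sleep fragmentation replicate 1 the S phase median was -0.06. The S phase call ended without replicate 1 of both groups (median -0.017) and with the late granule covariate (-0.035). The G2 and M phase call ended without control replicate 1 (median -0.03), control replicate 2 (-0.02) or sleep fragmentation replicate 2 (-0.01), and its median was -0.10 without sleep fragmentation replicate 3. It also ended without replicate 1 of both groups (-0.033), and the median was -0.11 with the late granule covariate. Scaled by library size only, which moves the median of all genes to -0.11, the medians were -0.22 and -0.16. Myc, a driver of growth, had 100.5 ± 13.4 against 83.2 ± 20.3 CPM.

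Siglecf, the receptor that names the mature neutrophils in the study's title and is also a marker of eosinophils, had 54.3 ± 4.02 CPM in control and 46.2 ± 2.06 CPM after sleep fragmentation (log2 fold change -0.23, SE 0.11). It did not pass edgeR's test (adjusted p = 0.99988). Of 23 genes linked to such neutrophils 15 had higher fitted levels (median log2 fold change 0.11), and camera did not call them (adjusted p = 0.055). By edgeR 0 passed, adjusted over the list alone or over all genes, with 3 higher at an unadjusted p under 0.05: Lgals3 (139.5 ± 22.3 against 219.7 ± 67.2 CPM), Cd300lb (58.7 ± 17.6 against 92.5 ± 30.4 CPM) and Cxcl3, which was at 1.45 CPM or less in each library. Of 35 inflammatory targets of NF-kB 27 had higher fitted levels, with a median of 0.24. Il1rn, the interleukin-1 receptor antagonist, had 26.3 ± 13.8 against 57.4 ± 18.3 CPM, and Nfkbia and Nlrp3 had log2 fold changes of 0.43 and 0.48. By edgeR 0 members passed, adjusted over the list alone or over all genes, with 2 higher at an unadjusted p under 0.05 (Il1rn and Cxcl3). Camera called this list (adjusted p = 5.4e-06), lost at adjusted p = 0.58 with an estimated correlation. Its median was 0.12 without control replicate 1, 0.45 without control replicate 2 and 0.14 when scaled by library size only. The call ended with the late granule covariate (median 0.06) and without replicate 1 of both groups (0.04).

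Clock genes and glucocorticoid targets, which sleep loss and stress hormones can alter in other settings, showed no shift as lists, though some clock genes had non-overlapping groups. Per1 had 18.5 ± 2.71 against 20.1 ± 2.14 CPM, and Fkbp5, a glucocorticoid target, 137.0 ± 10.6 against 145.6 ± 14.7 CPM. Of 18 clock genes 0 passed edgeR's test, adjusted over the list alone or over all genes, with 2 lower at an unadjusted p under 0.05, Per3 (45.4 ± 2.41 against 35.7 ± 4.82 CPM) and Nr1d1 (1.60 ± 0.40 against 0.78 ± 0.15 CPM). The groups did not overlap in 4 of the 18, Per3 and Nr1d1 among them, and all 4 were lower. Chance gives 10% for either direction, and the share over all genes was 6.75%. Per2 and Csnk1e had log2 fold changes of 0.38 and 0.29. The clock list (median -0.03, adjusted p = 0.48) and the 22 glucocorticoid-induced genes (median 0.12, adjusted p = 0.18) were not called by camera. Camera looks for a shift in a shared direction, so members that move in opposite ways can cancel.

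**Figure D3:**
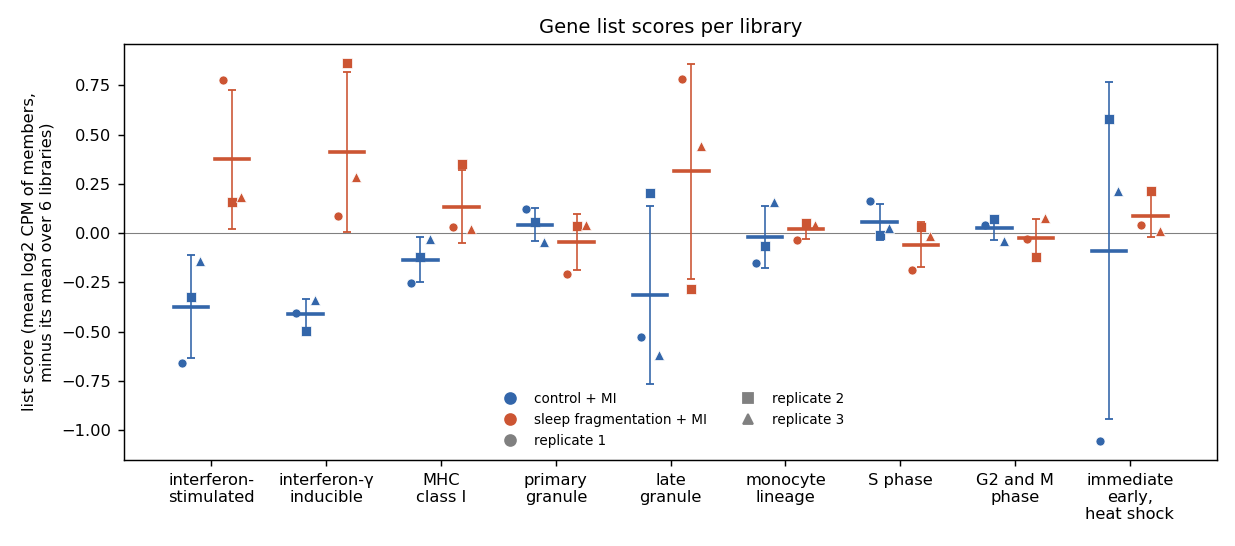
Scores of 9 gene lists in each library, as the mean log2 CPM of the members minus its mean over the 6 libraries. Symbols are replicates, horizontal lines are group means and error bars are SD (n = 3 per group). The groups are apart for interferon-stimulated genes (control at most -0.14, sleep fragmentation at least 0.16) and overlap for late granule genes. They are also apart for interferon-gamma-inducible genes (control at most -0.34, sleep fragmentation at least 0.09). The same holds, by a narrow gap, for MHC class I genes (control at most -0.030, sleep fragmentation at least 0.024).

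The shares of counts taken by markers of other marrow cells overlapped between the groups for each of the 8 lists of this kind. Basophil, eosinophil and mast cell genes took 0.59% ± 0.17 of counts in control and 0.55% ± 0.16 after sleep fragmentation (SD, n = 3). Erythroid genes took 0.027% ± 0.0056 of counts in control and 0.030% ± 0.0046 after sleep fragmentation (SD, n = 3), B-lymphoid genes 0.0032% ± 0.0008 and 0.0035% ± 0.0002, T and NK cell genes 0.0019% ± 0.0004 and 0.0022% ± 0.0007, and macrophage genes 0.154% ± 0.011 and 0.154% ± 0.0045. Megakaryocyte genes took 0.054% ± 0.0032 and 0.063% ± 0.0064, dendritic cell genes 0.035% ± 0.0020 and 0.033% ± 0.0021, and stromal and endothelial genes 0.0096% ± 0.0027 and 0.0080% ± 0.0029. Most of the megakaryocyte share came from 1 member, Rap1b (417.0 ± 45.2 against 523.6 ± 87.4 CPM). The members Pf4 (1.31 ± 0.94 against 3.05 ± 1.13 CPM) and Gp9 (1.47 ± 0.33 against 2.15 ± 1.19 CPM) added little to it. Late granule genes, which are not among these 8 lists, took 8.47% ± 1.97 of counts in control and 11.8% ± 4.11 after sleep fragmentation. Their share lay between 6.60% and 14.8% per library and also overlapped between the groups. Low shares of the 8 lists therefore do not show that the libraries were free of maturing neutrophils. Camera called the erythroid (median 0.48, adjusted p = 2.8e-04), macrophage (0.30, 2.8e-04) and B-lymphoid (0.38, 0.019) lists higher. These calls were lost with an estimated correlation (adjusted p = 0.58, 0.58 and 0.71 with an estimated correlation), and the list scores overlapped between the groups (exact permutation p = 0.4, 0.3 and 0.4, 2-sided). By edgeR 0 members of the 3 lists passed, adjusted over the list alone or over all genes. Of 20 erythroid genes 4 had non-overlapping groups, all higher, where chance gives 10%, namely Ermap (0.91 ± 0.15 against 2.004 ± 0.34 CPM), Car1 (2.71 ± 0.61 against 4.71 ± 0.94 CPM) and Klf1 (0.39 ± 0.16 against 0.97 ± 0.24 CPM), each at an unadjusted p under 0.05, and Hemgn (3.34 ± 0.19 against 4.75 ± 0.72 CPM). Of 20 macrophage genes 0 had an unadjusted p under 0.05. The erythroid call ended without control replicate 2 (median 0.26), and the median was 0.14 without sleep fragmentation replicate 3, 0.76 without sleep fragmentation replicate 2 and 0.84 without control replicate 3. The erythroid median was also 0.76 with the late granule covariate, and 0.33 when scaled by library size only. The B-lymphoid median was -0.05 without control replicate 2, 0.02 without sleep fragmentation replicate 3 and 1.07 without control replicate 3, and that call ended without either of the former, without control replicate 1 (0.25) or without sleep fragmentation replicate 2 (0.53). It also ended with DESeq2's fit (0.40), with a stricter filter on low counts (0.40) and without replicate 1 of both groups (0.28). Its median was 0.62 with limma-voom, 0.23 when scaled by library size only and 1.06 with the late granule covariate. The macrophage median lay between 0.09 without sleep fragmentation replicate 3 and 0.62 without control replicate 2. It was 0.18 without control replicate 1, 0.17 without control replicate 3 and 0.46 without sleep fragmentation replicate 2, 0.19 when scaled by library size only or without replicate 1 of both groups, and the call ended with the late granule covariate (0.006). Immediate early and heat shock genes, which respond to cell handling, were called higher by camera (median 0.21, mean 0.045, adjusted p = 0.016), lost at adjusted p = 0.73 with an estimated correlation. By edgeR 0 of 27 members passed, adjusted over the list alone or over all genes, with 0 at an unadjusted p under 0.05. Members went both ways: Ier5 and Socs3 had log2 fold changes of 0.71 and 0.59, whereas the heat shock genes Hspa1b, at 46.5 ± 48.3 against 13.7 ± 8.13 CPM, and Hspa1a, at 27.5 ± 28.4 against 7.495 ± 5.22 CPM, were highest in control replicate 2 (98.8 and 57.7 CPM). The list score was -1.05 in control replicate 1 against 0.01 or more in the other libraries. Without that library camera called the list lower (median -0.12, adjusted p = 0.0064). The median was 0.37 without control replicate 2 and 0.04, with no call, without sleep fragmentation replicate 2. It was 0.12 when scaled by library size only. The call also ended with DESeq2's fit (0.22), without replicate 1 of both groups (-0.060) and with the late granule covariate (-0.0030).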

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

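Leaving out replicate 1 of both groups and the late granule covariate were chosen after the data were seen. Across 23 alternatives, 1044 of 1070 values of named genes kept their direction and their side of the threshold, 20 changed direction and 6 newly passed. Among the values of gene lists, 213 kept both, 51 lost the call and 16 changed direction. The cause was not tested except where the construction shows it.

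DESeq2 called 13 genes (12 higher, 1 lower). An unadjusted p under 0.05 with a 1.5-fold change gave 210 genes (184 higher, 26 lower), a looser threshold by construction. With an estimated correlation and with fry, the lists of interferon-stimulated (median 0.56), primary granule (-0.15), late granule (0.62), S phase (-0.11) and G2 and M phase genes (-0.055) were not called, their medians being unchanged by construction. Library size alone moved the median of all genes to -0.11, which put Fkbp5 at -0.016 and Ifnar1 at -0.093. Ifnar1 was at -0.014 with upper-quartile factors. The monocyte median was 0.0029 with limma-voom.

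Replicate numbers did not pair the samples: same-numbered libraries had correlations of deviations of -0.25, -0.37 and -0.01, and 0 of 3 correlated best with their own number. With the replicate number as a block, 0 genes were called by edgeR and 169 had an unadjusted p under 0.05, 8 interferon-stimulated genes passed adjusted over the list alone, and the monocyte median was 0.0026. The block ended no list call made without it.

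Each library left out in turn gave medians of -0.22 to -0.042 for primary granule, -0.10 to -0.0091 for G2 and M phase, -0.12 (called lower) to 0.37 for immediate early and heat shock, -0.048 to 1.07 for B-lymphoid, -0.10 to 0.070 for monocyte and -0.36 to 0.047 for MYC target genes. Log2 fold changes were -0.061 to 0.056 for Ifnar1, -0.13 to 0.074 for Gfi1 and -0.44 to 0.016 for Irf8.

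Without replicate 1 of both groups, medians were 0.028 for primary granule, 0.026 for monocyte, 0.15 for MYC target (called higher) and -0.060 for immediate early and heat shock genes, and -0.017 for S phase and -0.033 for G2 and M phase genes, both no longer called with fewer samples. Log2 fold changes were -0.040 for Cebpe, -0.13 for Csf3r, -0.13 for Ifnar1 and 0.12 for Gfi1. With the late granule score as a covariate, the late granule median was -0.10, since the covariate was built from that list. The medians were 0.016 for primary granule, 0.16 for monocyte (newly called higher), -0.035 for S phase (not called), 0.31 for MYC target (called higher) and -0.0030 for immediate early and heat shock genes. Log2 fold changes were -0.075 for Ifnar1, -0.19 for Csf3r, -0.32 for Cebpe, 0.21 for Irf8, 0.021 for Mpo, 0.033 for Myc and -0.021 for Fkbp5.

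Total counts were alike in both groups. At this size the simulated test recovered 17.3% of 1.5-fold, 81.5% of 2-fold and 100% of 4-fold changes. The simulation held 200 changed genes per run, all with an average CPM of at least 5, and no structure among the samples. Each of these can raise the share recovered. The simulation therefore does not show whether the number of libraries accounts for 0 calls among genes such as Ifit1 (log2 fold change 2.71).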

Other observations

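The 10 splits of the libraries, for the sets of genes and terms fixed beforehand, were planned. The tests of a maturity difference, of a single library, of the range within groups, of exchanged labels and of the interferon members passing over the list alone were chosen after the results were seen.

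Targets of MYC and genes of ribosome biogenesis had a median log2 fold change of -0.11 over 44 genes and were called lower by camera (adjusted p = 0.019), lost at adjusted p = 0.80 with an estimated correlation. Of the 44, 5 had higher fitted levels. By edgeR 0 passed, adjusted over the list alone or over all genes. At an unadjusted p under 0.05 there were 0 lower members and 1 higher, Max (177.1 ± 32.2 against 235.7 ± 45.1 CPM), against the direction of the call. The call ended without control replicate 1 (median -0.03), control replicate 3 (-0.03) or sleep fragmentation replicate 1 (0.05), and the median was -0.28 without control replicate 2 and -0.36 without sleep fragmentation replicate 2. The call also ended when scaled by library size only (-0.20). Camera called the list higher without replicate 1 of both groups (median 0.15, adjusted p = 6.5e-05) and with the late granule covariate (0.31, adjusted p = 5.8e-23). Camera did not call stem and early progenitor genes (median -0.08, adjusted p = 0.066), inhibitors of the cell cycle and p53 targets (0.10, 0.058), regulators of neutrophil production (0.07, 0.55), components of interferon sensing and signalling (0.02, 0.38), ribosomal proteins (0.02, 0.44), oxidative phosphorylation (0.04, 0.49), glycolysis (0.05, 0.83), the unfolded protein response (-0.08, 0.18) or adrenergic and neural receptors (0.34, 0.20). The same held for megakaryocyte (0.14, 0.13), T and NK cell (0.42, 0.081), dendritic (-0.01, 0.94), basophil, eosinophil and mast cell (0.01, 0.55), and stromal and endothelial markers (-0.03, 0.27) and replication histones (0.06, 0.67). Among stromal markers Kitl passed edgeR's test (adjusted p = 0.032 over the list alone), at 0.04 ± 0.04 against 0.55 ± 0.23 CPM, close to the floor of detection.

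Of 2967 GO terms, camera called 99 higher and 27 lower after sleep fragmentation, and 0 of the 126 with an estimated correlation (adjusted p = 0.92 with an estimated correlation). Higher terms included cellular response to interferon-beta (40 genes, median 0.49), neutrophil chemotaxis (48 genes, 0.24) and response to bacterium (115 genes, 0.23). Lower terms included DNA replication (116 genes, -0.10) and aminoacyl-tRNA ligase activity (40 genes, -0.12). At least as many terms were called in 5 of the 10 splits of the libraries into 3 and 3, with 255 in the highest other split.

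Interferon-gamma-inducible genes, mostly GTPases, and interferon-stimulated genes peaked in different libraries. The score of the former was 0.86 in sleep fragmentation replicate 2 and 0.09 in replicate 1, whereas the score of the latter was 0.16 and 0.78. Among basophil, eosinophil and mast cell genes, Epx, eosinophil peroxidase, was at 708.6 ± 301.6 CPM in control and 600.7 ± 174.0 CPM after sleep fragmentation (SD, n = 3).

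Of 72 interferon-stimulated genes 69 had higher fitted levels after sleep fragmentation, of which 22 passed edgeR's test adjusted over the list alone and 0 over all genes, and camera's call was lost at adjusted p = 0.53 with an estimated correlation and at adjusted p = 0.70 with fry. Their median of 0.56 was the largest in absolute size among the 10 splits, with 0.44 in the highest other (1 of 10 splits as large). The count of 22 members passing over the list alone stood against 0 in each other split (1 of 10). Medians of 0.81 for the list of interferon-gamma-inducible genes, GTPases and others, against 0.53, and of 0.21 for MHC class I genes against 0.17, were likewise reached in 1 of 10 splits. With 10 splits no share can fall under 0.05.

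For the interferon-stimulated genes, a difference in maturity as the whole cause stays open: with the granule score as a covariate the median was 0.44 and 5 members passed over the list alone, but the score difference of 0.55 had a 95% interval over libraries from -0.46 to 1.57. Camera's call with the covariate (adjusted p = 9.4e-19) was lost at adjusted p = 0.72 with an estimated correlation. Within groups the scores do not decide it: control replicate 2, at a late granule score of 0.20 beside -0.53 and -0.62 in replicates 1 and 3, had an interferon-stimulated score of -0.32 between their -0.66 and -0.14, and sleep fragmentation replicates 1, 3 and 2, at late granule scores of 0.78, 0.44 and -0.28, had 0.78, 0.18 and 0.16. A single library as the whole cause is not decided either, since with so few libraries the interval is wide. Without sleep fragmentation replicate 1 the median was 0.33 and the score difference of 0.55 had an interval from -0.07 to 1.17. With each library left out in turn, the median lay between 0.33 and 0.64. With all 6 libraries the scores of the groups did not overlap, at 0.16 or more after sleep fragmentation against -0.14 or less in control. Leaving out a library cannot undo this, so it is no further test of a single library as the cause. An interferon response to sleep fragmentation itself stays open as a hypothesis, on which the 10 splits bear without deciding. More libraries per group would be needed to test it. Matching on the late granule score, or adjusting for it, could remove part of a response if sleep fragmentation itself alters that score. Whether it does is not known here, and the design text names differentiation into neutrophils.

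Of 47 late granule genes 46 had higher fitted levels after sleep fragmentation, of which 1 passed edgeR's test adjusted over the list alone and 0 over all genes, the groups' scores overlapped (exact permutation p = 0.2, 2-sided), and camera's call was lost at adjusted p = 0.58 with an estimated correlation. The range of this score within control was 1.31 times the group difference and within sleep fragmentation 1.70 times, which fits libraries that differ in maturity, or in how far the sort reached into maturing cells, whatever their group. The late granule median of 0.62 stood against 1.004 in the highest other split (2 of 10 as large), that of primary granule genes at 0.15 in absolute size against 0.19 (3 of 10), S phase at 0.11 against 0.13 (2 of 10), and G2 and M phase at 0.05 against 0.14 (6 of 10).

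The split that puts control replicate 2 with sleep fragmentation replicates 1 and 3, and sleep fragmentation replicate 2 with control replicates 1 and 3, called 1498 genes by edgeR, against 0 with the labels as given and 0 in each of the other 8 splits. That points to a structure of the samples other than the group. At least 341 genes with an unadjusted p under 0.05 were found in 5 of 10 splits, up to 3717, and with the labels as given the count lay between 155 without control replicate 1 and 1330 without sleep fragmentation replicate 2. An exchange of the labels of these 2 libraries could give this and so could a difference in maturity, and the 1498 genes do not decide between them. In the exchanged split the interferon-stimulated median was 0.37 in absolute size with 0 members passing over the list alone, the interferon-gamma-inducible median was 0.06 and the late granule median 1.004.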
